A study of Mus musculus with 14 samples.

How the data were processed

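RNA was sequenced from F4/80-positive macrophages taken with magnetic beads from tumours that 4T1 cells, a mouse mammary carcinoma line, had formed in Balb/c mice. Before injection the 4T1 cells were cultured for 5 days with DMSO, the vehicle, or with 5 µM GSK269962A, a small-molecule inhibitor. Macrophages were taken on day 8 (3 libraries per pre-treatment) and on day 14 (4 libraries per pre-treatment), which makes 14 libraries. The labels number the libraries within each group but do not state that each came from a separate mouse, so the p-values below measure the spread between these samples.

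The deposited file holds 1 table of log2-scale expression values, with 24556 mouse Ensembl genes and 14 columns, and every column was assigned to a library. The authors' notes name Bowtie2, RSEM 1.2.29 and DESeq2 1.12.4, with mm10 and GRCh38 as genome builds, and do not say which transformation gave the values. If it shrinks low genes, their changes are understated, which was not tested. No counts were used here, so the depth is unknown and no counting interval can be given. Gene symbols, coordinates and gene types were taken from the GENCODE M21 annotation of GRCm38, the assembly of the mm10 build, by exact Ensembl identifier, and 24470 of the 24556 identifiers matched while 86 did not.

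Genes were kept when their unlogged value was at least 10, which is 3.32 on the log2 scale, in at least 3 libraries, and 11886 genes were kept. A limma linear model (limma 3.58.1 in R 4.3.3) with 4 group means and an empirical Bayes trend was fitted to the deposited values of all 14 libraries. The comparisons were GSK269962A against DMSO on day 8, the same on day 14, the mean of these differences, the difference between them, and day 14 against day 8 within each pre-treatment. All tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the kept genes of each comparison, with 0.05 as the threshold. Unless another error is named, "SE" beside a log2 change is the standard error of the limma fit.

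The comparisons, the filter, the gene lists, the rule for named genes and a first set of other settings were fixed before the data were examined. There were 33 gene lists, among them macrophage states (classical and alternative activation, lipid-associated, resident-like, monocyte, pan-macrophage), interferon response, MHC class I and class II, NF-kB targets, chemokines, hypoxia and glycolysis, nuclear oxidative phosphorylation, matrix and angiogenic factors, checkpoint genes, cell cycle, cholesterol synthesis, tissue dissociation with immediate-early response, unfolded protein response, phagocytosis receptors, ribosomal proteins, mitochondrially encoded genes, and markers of 4T1 epithelium, neutrophils, T and NK cells, B and plasma cells, fibroblasts, endothelium, dendritic cells, eosinophils with basophils and mast cells, erythroid cells, and fat pad. Each list with at least 3 kept genes was tested against all other genes with camera at a preset correlation of 0.01, and again at an estimated correlation. Each was also tested with fry, which tests a list against no change and not against other genes. The fat pad list held 2 kept genes and was not tested, which left 32 lists, over which p-values were adjusted within each comparison.

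The rule for named genes took, in each comparison, up to 10 genes higher and 10 genes lower with the largest log2 change among those past the threshold, with an unlogged group mean of at least 50 and no overlap between the libraries compared. Numbered Gm and Rik models and antigen receptor segments were left out, and where fewer than 5 genes passed in a direction the genes with the smallest p filled up to 5. The rule also took up to 4 members past the threshold from each list, and always Adgre1, Arg1, Mrc1, Nos2, Cd274, Spp1, Il1b, Ccl2, Vegfa, Tgfb1 and H2-Ab1. The text gives only part of the list members that the rule took, and that part was chosen after their values were seen. Among the genes always given, several small differences that did not pass turned sign when 1 library was left out, and the text gives this only for Mrc1.

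The settings fixed then were pseudocounts of 0.1 and 10 on the unlogged values, no filter, a minimum of 50, rescaling by unweighted TMM factors, quantile normalisation, limma without the trend, library quality weights, the replicate number as a block, a fit of only the groups compared, an estimated correlation for the lists, and leaving out each library. Chosen after the data were seen were removal of each library's trend with GC content, leaving out genes that share at least 10% of their 31-base words with another gene, the mean of the 4T1 epithelium list as a covariate, which of a pair of overlapping ribosomal RNA genes holds the reads as a batch term or as a restriction to 1 kind of library, and leaving out the first library of both day 8 groups. Other splits of the same libraries were refitted, at most 100 for each comparison. The fit was tested on simulated data with 100 genes moved by a log2 change of 1 and another 100 by 2. Of the former it recovered 81% on day 8 with 7 false calls and 86% on day 14 with 8 false calls. The simulated noise was independent between libraries, with 1 SD per gene, and held none of the structure of the real libraries. These shares therefore test the fit and do not give its recovery in the real data. The authors' tools were not rerun, since no reads or counts were used here.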

Results

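Gene expression was measured in macrophages from 4T1 mammary tumours whose tumour cells had been exposed, before injection, to DMSO or to the small-molecule inhibitor GSK269962A. The DMSO and GSK groups below refer to that pre-treatment of the tumour cells. The word macrophages below stands for the isolated fractions. In every comparison, changes within macrophages were not told apart from changes in which cells the fractions held. There were 3 DMSO and 3 GSK libraries from day 8 and 4 DMSO and 4 GSK libraries from day 14. Values are on the authors' log2 scale, coordinates are those of the GRCm38 assembly, and the depth of the libraries is unknown because no counts were used here.

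All 4 GSK day 14 libraries lay apart from the other 10 on the first principal component, which held 40.8% of the variance. Pearson correlations between libraries of the same group lay between 0.967 and 0.993. Pairs from different groups could be as close. GSK day 8 library 3 had a correlation of 0.990 with GSK day 14 library 2 and with DMSO day 14 library 3. With library 1 of its own group it had 0.972. A pair of overlapping ribosomal RNA genes on chromosome 17 split the libraries in a way that the groups do not give: 9 libraries had their signal on AY036118 and 5 had it on Gm42418. The 9 were all 4 GSK day 14 libraries, 2 DMSO day 14, 2 GSK day 8 and 1 DMSO day 8 library, so this split was uneven across the groups and values within each kind of library are given beside each comparison. As a term in the model it was past the threshold for 41 genes. On the first principal component the 5 libraries with Gm42418 high had scores from -37.9 to -9.89. The 9 with AY036118 high had scores from -21.2 to 43.1, so this component is not free of the split.

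**Figure D1:**
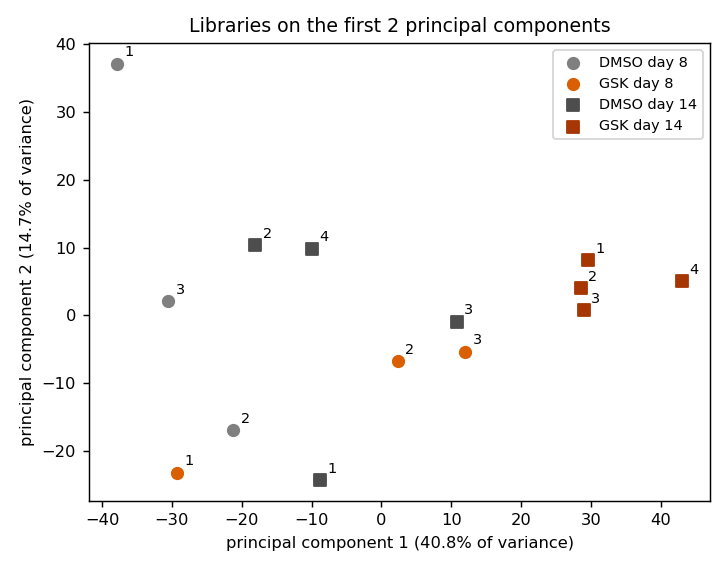
Scores of the 14 libraries on principal component 1 (40.8% of variance) and principal component 2 (14.7%), with 1 point per library and the number of the library beside it. The GSK day 14 libraries sit at the right, with scores from 28.6 to 43.1, and the highest score of any other library is 12.0.

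Day 8 asks how pre-treatment of the tumour cells altered macrophages of young tumours. The mean of the 4T1 epithelium list was 5.72 ± 0.40 in DMSO and 6.19 ± 0.62 in GSK fractions (SD, n = 3 each). A different share of tumour cells in the fractions was therefore not separable from a change within macrophages. In GSK tumours, macrophages had less Slc17a9, a vesicular nucleotide transporter, by a log2 change of -1.84 (SE 0.26, 3.59-fold lower), from 9.17 ± 0.55 to 7.32 ± 0.18 (SD, n = 3 each; adjusted p = 0.0311, limma). They had more Hsph1, a heat-shock protein of the list for tissue dissociation and immediate-early response, by 1.10 (SE 0.21, 2.15-fold higher). Krt14, a keratin of the 4T1 epithelium list, rose by 1.37 (SE 0.25), from a low level of 4.14 ± 0.59 to 5.50 ± 0.46 (SD, n = 3 each). It shares 29.2% of its 31-base words with other genes. Of 11886 genes, 7 rose and 16 fell, and 1939 had an unadjusted p under 0.05. Of these 23 genes, 13 share at least 10% of their 31-base words with other genes (0.456% of 2851 such genes, against 0.0682% of 5867 genes with under 1%).

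Slc17a9 (ENSMUSG00000023393) lies on chromosome 2 from 180725263 to 180742280. Also lower were Lrrc17 (log2 change -1.71), Akap5, an anchoring protein for protein kinase A (-1.66), the nuclear import receptor Tnpo3 (-1.25), the centromere protein gene Cenpc1 (-1.24), Selenot (-1.06), Ccdc22 (-1.04), Klhl21 (-0.94) and the kinesin gene Kif3a (-0.93). The ribosomal protein pseudogenes Rpl17-ps3 (log2 change 2.65) and Rps6-ps4 (2.83-fold) were higher and Rps2-ps10 (-1.07) was lower. These pseudogenes share 90.3%, 100% and 96.7% of their 31-base words with other genes, and Ccdc22 shares 90.7%. Lrrc17 and Akap5 share words with each other and had a Pearson correlation of 0.998 over all libraries, so they do not count as separate results. AW112010 (0.77) and Stoml1 (0.79) did not pass, at an adjusted p of 0.0530 each. Beyond the genes already named, the 7 that rose and 16 that fell are mostly numbered gene models, which the naming rule leaves out.

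The MHC class II list, whose genes present antigen to CD4 T cells, was higher than other genes (median log2 change 0.51, 9 of 10 positive, camera adjusted p = 0.00553). No member passed over all genes in limma, and 5 of the 10 rose when adjusted over the list alone. The interferon list was also higher (median 0.21, 26 of 32 positive, adjusted p = 0.0103), with 0 members past the limma threshold over all genes and 2 when adjusted over the list alone. So was the 4T1 epithelium list (median 0.35, 13 of 14 positive, adjusted p = 0.0269), with 1 member past the threshold over all genes and 2 when adjusted over the list alone. In fry no list passed (lowest adjusted p = 0.0597), and with an estimated correlation none of the 3 calls held, at an adjusted p of 0.560 for class II and for interferon and an adjusted p of 0.907 for epithelium. The other 29 lists did not pass (adjusted p from 0.120 to 0.879). Of the genes always given, none passed in limma: H2-Ab1 differed by 0.61 (adjusted p = 0.0934), Il1b by 0.54, Mrc1 by -0.50 (0.02 without GSK day 8 library 1), Tgfb1 by -0.27, Adgre1 by 0.27, Spp1 by -0.23, Arg1 by 0.18, Vegfa by 0.15, Ccl2 by -0.04, Nos2 by -0.02 and Cd274 by 0.01.

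The day 8 count depended on single libraries. In limma it was 0 without DMSO day 8 library 1 (1327 genes at an unadjusted p under 0.05), 0 without GSK day 8 library 2 (1488) and 0 without GSK day 8 library 3 (1381), and it was 208 without DMSO day 8 library 2, 52 without DMSO day 8 library 3 and 201 without GSK day 8 library 1. Day 14 libraries enter through the shared variance: the count was 71, 41, 54 and 2 without DMSO day 14 libraries 1 to 4 and 1, 1, 3 and 5 without GSK day 14 libraries 1 to 4. Among libraries with AY036118 high, 76 genes passed, 54 higher and 22 lower, of which 12 were among the 23, and among those with Gm42418 high 3 passed, of which 0 were. The former fit has 1 DMSO day 8 library and the latter 1 GSK day 8 library, and each lone library is assumed to vary like the other groups. The balance of directions also turned without the first library of both day 8 groups (24 higher, 21 lower) and in a fit of only the groups compared (2 higher, 0 lower; limma, 1175 at an unadjusted p under 0.05). The 4T1 epithelium call ended without DMSO day 8 library 1 (adjusted p = 0.245) or 2 (0.210) and without GSK day 8 library 1 (0.423) or 2 (0.213), and the interferon call ended without DMSO day 8 library 1 (0.113) or GSK day 8 library 3 (0.0592). With the 4T1 epithelium mean as a covariate 0 genes passed on day 8 in limma (1809 at an unadjusted p under 0.05). With the ribosomal RNA split as a term 8 passed, of which 7 were among the 23. Libraries of the compared groups did not overlap for 16.2% of genes, where chance gives 10%.

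Day 14 asks the same of older tumours, and far more genes passed the threshold. The counts do not measure a growth of the difference, since day 14 had 4 libraries per group and day 8 had 3. The direct test of such a growth, the interaction given below, called 1 gene. Macrophages from GSK tumours had less Klf2, a transcription factor of the dissociation and immediate-early list, which marks tissue handling as well, by a log2 change of -1.25 (SE 0.23, 2.38-fold lower), from 13.03 ± 0.35 to 11.77 ± 0.29 (SD, n = 4 each; adjusted p = 0.00694, limma). The chemokine Ccl4 fell by 1.10 (SE 0.19), from 11.24 ± 0.35 to 10.13 ± 0.13, while the cytokine Il1b rose by 0.69 (SE 0.16), from 13.23 ± 0.18 to 13.92 ± 0.19 (SD, n = 4 each). The alternative-activation marker Chil3 rose by 1.72 (SE 0.33, 3.29-fold higher), and the lactate exporter Slc16a3 was 2.29-fold lower. Of 11886 genes, 606 rose and 681 fell, 3240 had an unadjusted p under 0.05, and groups did not overlap for 22.0% of genes, where chance gives 2.86%.

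**Figure D2:**
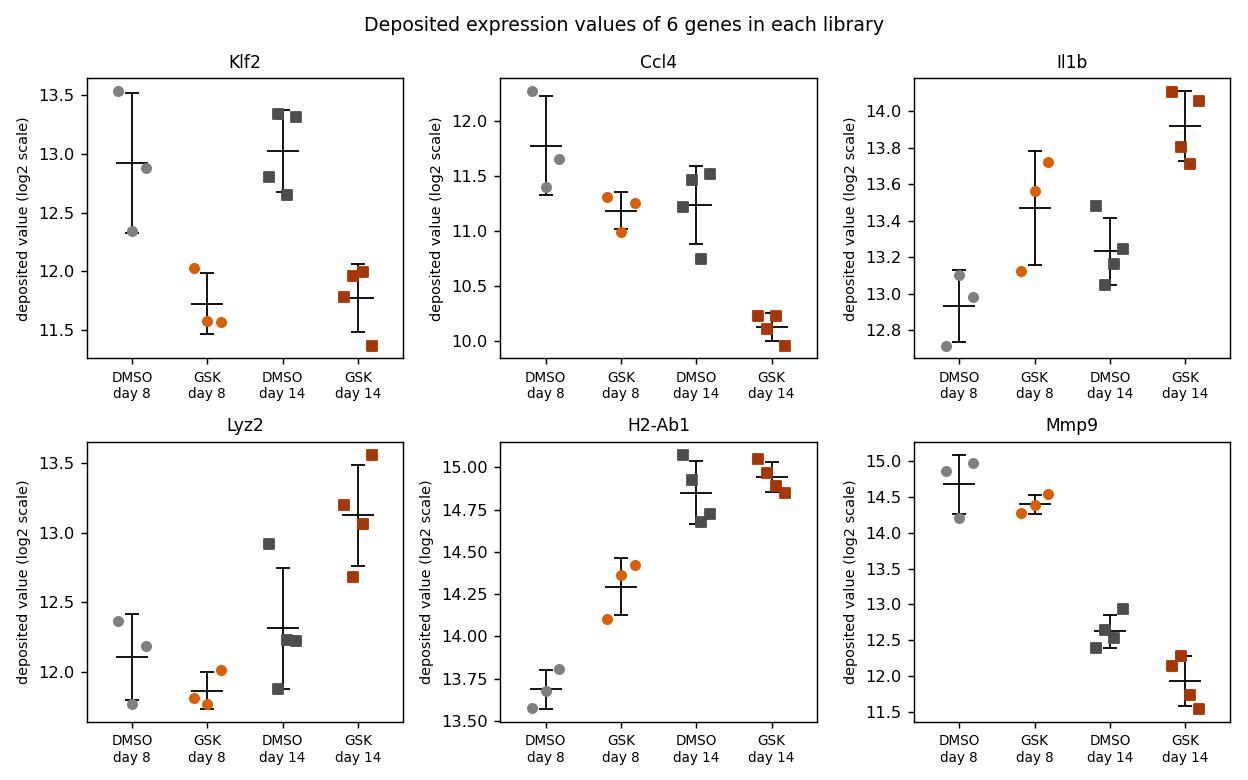
Deposited log2-scale values of Klf2, Ccl4, Il1b, Lyz2, H2-Ab1 and Mmp9 in each library by group, with 1 point per library and lines for the mean ± SD (n = 3 on day 8, n = 4 on day 14); each panel has its own vertical range, which does not start at 0. On day 14 the Klf2 mean was 13.03 in DMSO and 11.77 in GSK libraries, and Mmp9 fell with time in both pre-treatments, to 12.62 and 11.93.

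Named macrophage genes of the fixed lists moved both ways on day 14. In the classical activation list 3 of 21 rose and 2 fell, and 5 rose and 2 fell when adjusted over the list alone. They included Il1b, the cytokine Il6 (0.70) and the co-stimulatory gene Cd86 (0.80), which rose, and the formyl peptide receptor Fpr2 (-0.92), which fell. In the alternative activation list 6 of 21 rose and 1 fell, and 8 rose and 1 fell when adjusted over the list alone, with Retnla at 1.39 and Mgl2 at 0.77 beside Chil3. Of 16 pan-macrophage genes 5 rose and 2 fell, and 6 rose and 2 fell when adjusted over the list alone. Lysozyme gene Lyz2 rose by 0.81, the adaptor Tyrobp by 0.96 and Cd33 by 0.57, and the integrin Itgam fell by 0.59. The resident-like list had 2 higher and 2 lower of 18 (3 and 2 when adjusted over the list alone), with Selenop at 1.57, the complement gene C1qa at -0.85 and Cbr2 at -0.88. The lipid-associated list had 4 higher and 2 lower of 20 (5 and 2 when adjusted over the list alone), among them the tetraspanins Cd63 (0.78) and Cd9 (1.05). Phagocytosis receptors had 2 higher and 2 lower of 17 (2 and 2 when adjusted over the list alone), with the inhibitory Fc receptor Fcgr2b and the integrin Itgb2 higher (1.15 and 0.63) and Fcgr4 lower (-0.85).

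Members of other lists also passed. Among NF-kB targets 2 of 24 fell, Ccl4 and Ier3 (-0.50), and 3 rose and 2 fell when adjusted over the list alone. Hypoxia and glycolysis genes had 2 of 27 lower, Slc16a3 and the phosphofructokinase Pfkl (-0.73), with 2 higher and 2 lower when adjusted over the list alone. In the dissociation and immediate-early list Jund (-1.03, 31.3% of words shared) fell with Klf2 and Hsph1 (0.62) rose, 3 of 18. The same count passed when adjusted over the list alone. Cholesterol genes had 3 of 22 lower (5 when adjusted over the list alone), with Cyp51 at -0.58. In the class II list H2-Eb1 (0.93) and the protease Ctss (0.66) rose, 2 of 10, and 3 rose and 2 fell when adjusted over the list alone. Lilrb4a (1.40) and Havcr2 (0.58), inhibitory receptors of the checkpoint list, rose, 2 of 16, and 4 rose when adjusted over the list alone. Ribosomal protein genes had 2 of 25 higher and 6 lower (3 and 6 when adjusted over the list alone), among them Rpl4 (1.35) and Rpl8 (-0.94). The matrix protease Mmp9 fell by 0.70. Igkc, a marker of B and plasma cells, fell by 0.57, and no gene of the 4T1 epithelium, endothelium or fibroblast lists passed in limma, over all genes or when adjusted over the list alone.

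Mitochondrially encoded genes, which are also read as a sign of RNA quality, rose on day 14 as a list (median 0.88, 12 of 13 positive, camera adjusted p = 0.000179). Over all genes 5 of 13 rose, 7 when adjusted over the list alone, with mt-Nd6 at 1.07, mt-Nd1 at 1.06, mt-Cytb at 1.00 and mt-Co1 at 0.99. This call ended with an estimated correlation (adjusted p = 0.839) and did not pass in fry (adjusted p = 0.0939), and the other 31 lists did not pass (adjusted p from 0.205 to 0.989). The largest named changes were mostly in genes that share sequence with others. Rps6-ps4 rose by 6.59 (SE 0.24) and Rpl17-ps3 by 3.33, Rpl39-ps by 2.38, Rpl30-ps10 by 2.22 and Rpl36a-ps2 by 2.09, as did Rpl35a-ps2, Rpl35a-ps3 and Rpl35a-ps4 (1.98 for Rpl35a-ps2). Of 281 processed pseudogenes, 50 rose and 16 fell, and of 179 antisense genes 0 rose and 14 fell. Also higher were the dynein light chain Dynlt1b (2.42, 83.7% of words shared) and Fbxl2 (2.15, 13.6% shared). Lower were Mid1-ps1 (-2.35), Ccdc36 (-1.65), the creatine kinase Ckb (-1.64) and Rps12-ps11 with 6 further copies, Rps12-ps12, Rps12-ps13, Rps12-ps14, Rps12-ps15, Rps12-ps17 and Rps12-ps18 (-1.45 for Rps12-ps11).

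Of the genes always given, Il1b and Adgre1 passed on day 14. Adgre1 encodes F4/80, the marker used for isolation, and rose by 0.70 (SE 0.21). Vegfa differed by 0.46 (adjusted p = 0.0536), Spp1 by 0.63, Tgfb1 by -0.48, Ccl2 by -0.24, Mrc1 by 0.20 (-0.32 without DMSO day 14 library 1), Cd274 by -0.13, H2-Ab1 by 0.09, Nos2 by 0.06 and Arg1 by -0.03, none past the threshold in limma. Leaving out 1 library left 221 calls without GSK day 14 library 4, 327 without DMSO day 14 library 2, 648 without DMSO day 14 library 4, 668, 702 and 768 without GSK day 14 libraries 1, 3 and 2, and 825 without DMSO day 14 library 1. Among libraries with AY036118 high 860 genes passed, 477 higher and 383 lower, 637 of them among the 1287, while the other kind held no GSK day 14 library; with the split as a term 362 passed and with the 4T1 epithelium mean as a covariate 571.

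Averaged over both days, which asks what pre-treatment changed in the mean of the day 8 and day 14 differences, 800 genes rose and 924 fell in GSK tumours. Klf2 fell by 1.22 (SE 0.18, 2.34-fold lower), Slc17a9 by 1.46 (SE 0.17), Akap5 by 1.43 and Lrrc17 by 1.45, in libraries that did not overlap on either day. Akap5 and Lrrc17 share sequence and had a Pearson correlation of 0.998 over all libraries, so their falls do not count as separate results. Retnla, a secreted marker of alternative activation, rose by 1.28 (SE 0.27, 2.43-fold higher), and Adap2 by 1.21 (SE 0.16). Interferon-response genes were higher as a list (median 0.20, 26 of 32 positive, camera adjusted p = 0.0219; 0.803 with an estimated correlation, fry adjusted p = 0.0223), with the RNA sensor Ifih1 at 0.63, Mx2 at 0.48, Oas1a at 0.38 and Ifi44 at 0.37. Over all genes 5 of these 32 rose, 8 when adjusted over the list alone.

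The mitochondrially encoded list was again higher (median 0.47, adjusted p = 0.0219; 4 of 13 rose, 7 when adjusted over the list alone), with mt-Co1 at 0.65 and the mitochondrial ribosomal RNA mt-Rnr2 at 1.24. With an estimated correlation this call ended too (adjusted p = 0.803), in fry it did not pass (adjusted p = 0.112), and the other 30 lists did not pass (adjusted p from 0.169 to 0.921). In the class II list 5 of 10 rose (5 rose and 1 fell when adjusted over the list alone), with H2-Eb1 at 0.89, Ctss at 0.62, H2-Aa at 0.61, H2-DMa at 0.52 and H2-Ab1 at 0.35, but the list did not pass in camera (adjusted p = 0.169). The interleukin Il1b rose by 0.61, the chemokine Cxcl2 by 0.60, the receptor antagonist Il1rn by 0.29 and Adgre1 by 0.49. Also lower were the phosphatase Dusp5 (-1.44), Ckb (-1.44), Ccdc36 (-1.46), AC061963.1 (-1.45), the glycogen synthase Gys1 (-1.24) and Mid1-ps1 (-2.66). Also higher were the small nucleolar RNA Snord89 (1.34), Fbxl2 (1.92) and the pseudogenes Rps6-ps4 (4.05), Rpl17-ps3 (2.99), Rpl18-ps2 (1.72), Rpl28-ps1 (1.69) and Rpl27-ps3 (1.21). Among the genes always given, Vegfa (0.31), Tgfb1 (-0.38), Spp1 (0.20), Mrc1 (-0.15), Ccl2 (-0.14), Arg1 (0.07), Cd274 (-0.06) and Nos2 (0.02) did not pass. The count fell to 786 without GSK day 8 library 3, 970 without GSK day 8 library 2 and 951 without GSK day 14 library 4, and it was 1145 without DMSO day 14 library 2; with AY036118 high, where DMSO day 8 has 1 library, 1463 passed, and with the split as a term 629. The interferon call ended without DMSO day 8 library 1 (adjusted p = 0.0688), GSK day 8 library 1 (0.0947) or DMSO day 14 library 3 (0.0838), and the mitochondrial call without the first (0.0688) or the second of these (0.151).

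Whether the pre-treatment difference itself changed from day 8 to day 14 was tested as an interaction, and 1 gene passed. Rps6-ps4, a ribosomal protein pseudogene on chromosome 2, had a difference larger by 5.09 on day 14, and all of its 31-base words occur in another gene. Of the 11886 genes, 987 had an unadjusted p under 0.05. The difference of mitochondrially encoded genes was higher on day 14 than on day 8 (median 0.66, 11 of 13 positive) and that of 4T1 epithelium genes lower (median -0.65, 11 of 14 negative), each with a camera adjusted p of 0.000442. Epithelium means were 5.72 in DMSO and 6.19 in GSK libraries on day 8, and 5.07 and 4.83 on day 14. In limma 0 members of either list passed over all genes, and 2 mitochondrial genes rose and 2 epithelium genes fell when adjusted over the list alone. Both calls ended with an estimated correlation (adjusted p = 0.767 each) and did not pass in fry (adjusted p = 0.511 each), and the other 30 lists did not pass (adjusted p from 0.0693 to 0.987). The gene count rose to 12 without GSK day 14 library 1, 8 without GSK day 14 library 2 and 2 without DMSO day 8 library 1, and it was 12 with AY036118 high, where DMSO day 8 has 1 library. Across the 11886 genes, which are not independent replicates, the day 8 and day 14 differences had a Pearson correlation of 0.509 and a Spearman correlation of 0.456.

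**Figure D3:**
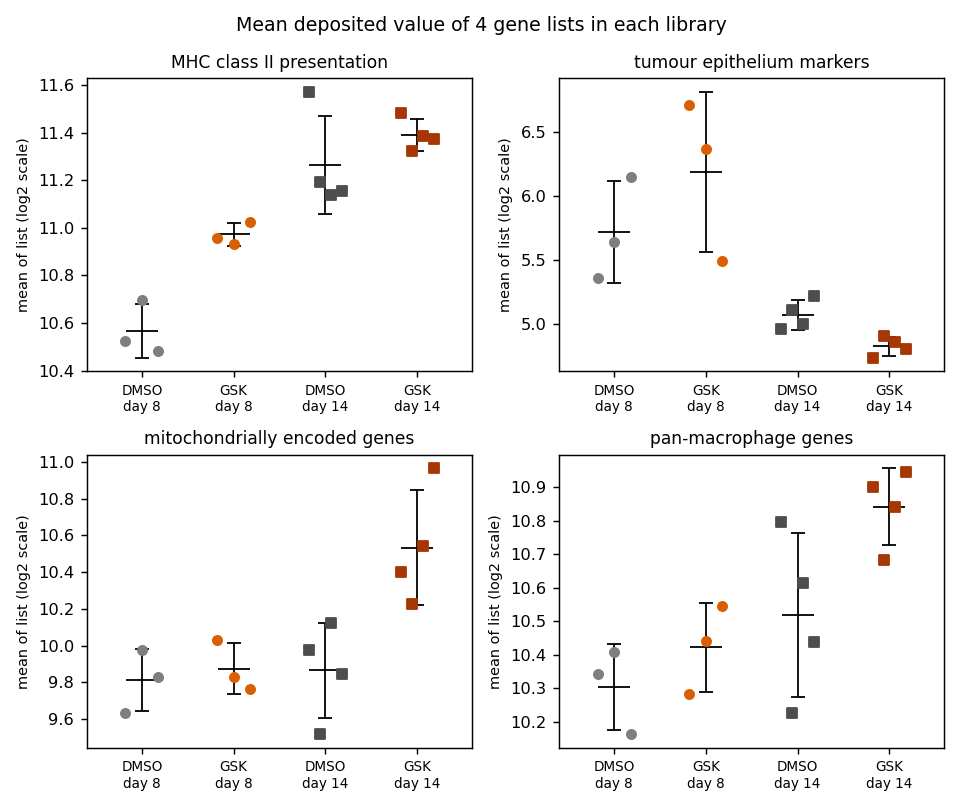
Mean log2-scale value of the MHC class II, tumour epithelium, mitochondrially encoded and pan-macrophage lists in each library by group, with 1 point per library and lines for the mean ± SD (n = 3 on day 8, n = 4 on day 14); vertical ranges differ and do not start at 0. Class II means rose from 10.57 to 11.26 in DMSO tumours, and epithelium means fell from 6.19 to 4.83 in GSK tumours.

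Time after DMSO pre-treatment compares the isolated fractions of control tumours on day 8 and day 14. Lists of epithelium, endothelium and fibroblast genes fell as well, as given below. Changes within macrophages were therefore not told apart from changes in which cells the fractions held. Tumour growth was also not separable from the day of harvest and isolation. From day 8 to day 14 the matrix protease Mmp9 fell by 2.05 (SE 0.21, 4.14-fold lower), from 14.68 ± 0.41 (SD, n = 3) to 12.62 ± 0.23 (SD, n = 4; adjusted p = 0.000445, limma), and the scavenger receptor Cd163 fell by 1.78 (SE 0.24). Of the MHC class II genes, 4 of 10 rose: H2-Ab1 by 1.16 (SE 0.15, 2.24-fold higher), H2-Eb1 by 1.25, H2-Aa by 1.14 and Cd74, the class II chaperone, by 1.01. Of 11886 genes, 36 rose and 62 fell, 1828 had an unadjusted p under 0.05, and groups did not overlap for 10.1% of genes, where chance gives 5.71%.

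The class II list rose as a whole (median 0.66, 9 of 10 positive, camera adjusted p = 1.3e-08, fry adjusted p = 0.000798), with 4 members higher over all genes and 8 when adjusted over the list alone. With an estimated correlation its adjusted p was 0.0663. Lists of other cell types fell together: 4T1 epithelium (median -0.46, 14 of 14 negative, adjusted p = 3.2e-05), endothelium (-0.40, 14 of 14, adjusted p = 3.84e-05) and fibroblast (-0.25, 10 of 10, adjusted p = 0.00727). With an estimated correlation their adjusted p was 0.369, 0.359 and 0.266. Of the epithelium list the tight-junction gene Cldn7 (-1.19) passed over all genes and 5 fell when adjusted over the list alone; for endothelium these counts were 0 and 4 and for fibroblast 0 and 2 in limma. Phagocytosis receptors (median 0.22, adjusted p = 0.0172) and B and plasma cell markers (median 0.38, adjusted p = 0.0423) were higher, both with an adjusted p of 0.359 with an estimated correlation. Of these, the receptor kinase Axl (1.11) and Igkc (1.00) passed over all genes, 1 in each list, and 2 in each list rose when adjusted over the list alone. The other 26 lists did not pass (adjusted p from 0.0779 to 0.875).

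Other genes that fell were the neutrophil-attracting chemokine Cxcl5 (-1.79), Zfp575 (-1.69), the ubiquitin-like Ubd (-1.66), the small nucleolar RNA gene Rnu3b1 with the copies Rnu3b2, Rnu3b3 and Rnu3b4 (-1.58 for Rnu3b1), the basement-membrane proteoglycan Hspg2 (-1.56), smooth-muscle actin Acta2 (-1.18), the chemokine Ccl24 (-0.95) and Gata2 (-0.90). The lectin receptors Clec12a (1.54) and Clec4a3 (1.09), the adhesion gene Cadm1 (1.37), Pid1 (1.14), Tmem176b (1.06) and complement C4b (1.04, 48.8% of words shared) rose. Of the genes always given only H2-Ab1 passed; Vegfa differed by 0.42, Mrc1 by -0.38 (0.13 without DMSO day 14 library 1), Il1b by 0.30, Adgre1 by 0.29, Nos2 by 0.23, Cd274 by -0.22, Tgfb1 by 0.18, Arg1 by 0.11, Ccl2 by 0.05 and Spp1 by -0.04. The count ranged from 24 without DMSO day 8 library 3 and 30 without DMSO day 8 library 1 to 305 without DMSO day 8 library 2. It was 188 and 48 without GSK day 8 libraries 1 and 2, 37 and 36 without DMSO day 14 libraries 2 and 3, and 38, 35, 41 and 60 without GSK day 14 libraries 1 to 4. Among libraries with AY036118 high 26 genes passed, 20 higher and 6 lower, of which 6 were among the 98, with 1 DMSO day 8 library that is assumed to vary like the other groups, with Gm42418 high 1, with the split as a term 115, and with the 4T1 epithelium mean as a covariate 3. The phagocytosis and B cell calls ended without DMSO day 8 library 3 (adjusted p = 0.180 each) or DMSO day 14 library 1 (0.130 each), the B cell call also without DMSO day 8 library 2 (0.0673), GSK day 8 library 1 (0.0617) or GSK day 8 library 3 (0.0547), and the fibroblast call without DMSO day 8 library 3 (0.0632).

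Time after GSK pre-treatment shows the same interval in the treated arm, with the same limits on what can be told apart. Tumour epithelium markers fell: Krt18 by 2.95 (SE 0.42, 7.73-fold lower), from 9.55 ± 1.32 (SD, n = 3) to 6.60 ± 0.29 (SD, n = 4; adjusted p = 0.00198, limma), as did the keratins Krt7 (-2.28), Krt19 (-1.98) and Krt14 (-1.97). Mmp9 fell by 2.47 (SE 0.21, 5.54-fold lower) and the cytokine Tnf by 1.84 (SE 0.20). Also, Lyz2 rose by 1.26 (SE 0.23), the GM-CSF receptor Csf2ra by 1.73 (SE 0.26) and the chemokine receptor Cx3cr1 by 1.15 (SE 0.26). Of 11886 genes, 363 rose and 470 fell, 2954 had an unadjusted p under 0.05, and groups did not overlap for 30.3% of genes, where chance gives 5.71%.

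The 4T1 epithelium list fell (median -1.52, 13 of 14 negative, camera adjusted p = 3.11e-10), with 9 members lower over all genes and 11 when adjusted over the list alone, Cldn4 (-1.70) and Wfdc2 (-2.51) among them. Endothelium fell (median -0.46, adjusted p = 0.00958), with the endothelial Plvap (-1.91) and Pecam1 (-0.71) lower, 2 of 14, and 5 when adjusted over the list alone. With the 4T1 epithelium mean as a covariate the endothelium list (0.28) and Plvap (0.63) turned to higher, neither past the threshold. Mitochondrially encoded genes rose (median 0.84, adjusted p = 0.000134), 5 of 13 over all genes and 8 when adjusted over the list alone. Pan-macrophage genes (median 0.42, adjusted p = 0.00774) and class II genes (median 0.43, adjusted p = 0.00774) rose, 2 of 16 and 4 of 10 over all genes, and 6 and 5 when adjusted over the list alone. In class II, H2-Eb1 rose by 1.32, H2-Aa by 1.00 and H2-Ab1 by 0.65, and 1 member fell. Phagocytosis receptors rose (median 0.27, adjusted p = 0.0220), 2 of 17, with Itgb2 at 0.93 and Axl at 0.90, and 2 when adjusted over the list alone. With an estimated correlation all 6 calls ended, at an adjusted p of 0.357 for epithelium, mitochondrial, class II and phagocytosis lists and 0.391 for endothelium and pan-macrophage. The other 26 lists did not pass (adjusted p from 0.0836 to 0.992).

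Also higher were Chil3 (2.09), the nucleosome-binding Hmgn2 (1.98), C1rb (1.98), the protease inhibitor Cst3 (1.61), Mgst1 (1.61), Havcr2 (1.04), Vegfa (0.74), Dynlt1b (2.51), Rps6-ps4 (4.49), Rpl30-ps10 (2.34) and Rpl39-ps (2.22). The monocyte receptor Ccr2 rose by 0.91. Also lower were Rnu3a (-3.58, SE 0.95), Clu (-2.67), the caveolae gene Cavin1 (-1.91), and the globin genes Hba-a2 (-1.90) and Hba-a1 (-1.44). With the 4T1 epithelium mean as a covariate Cavin1 (0.06), Hba-a2 (0.29) and Hba-a1 (0.47) turned to higher, none past the threshold. Of the genes always given Vegfa and H2-Ab1 passed, while Spp1 (0.82), Adgre1 (0.71), Il1b (0.45), Cd274 (-0.36), Nos2 (0.31), Mrc1 (0.31; -0.21 without GSK day 8 library 1), Ccl2 (-0.14), Arg1 (-0.11) and Tgfb1 (-0.02) did not. The count was 112 without GSK day 8 library 1, 170 without GSK day 14 library 4, 237 without GSK day 8 library 2, 247, 378 and 449 without GSK day 14 libraries 1, 2 and 3, and 1 with the 4T1 epithelium mean as a covariate. Among libraries with AY036118 high 290 genes passed, with the split as a term 471, and the endothelium call ended without GSK day 8 library 1 (adjusted p = 0.0508).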

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

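The tests of shared reads, of the ribosomal RNA split, of sequence shared with Lrrc17, of the class II list against the pan-macrophage list and of splits for the correlation were chosen after the results were seen, while the other split tests were chosen before; the GC correction was added after the data were seen, and its test was set before its own result was. The ribosomal RNA test was first set as the median ratio of the day 14 change among libraries with AY036118 high to that among all libraries, was 0.914, and was replaced because it ran on genes chosen for the pattern. Another 2 tests were tried and are not weighed: across genes, the day 14 changes had an absolute Spearman correlation of 0.113 with the main axis of variation within day 8 groups, and the summed signal of both ribosomal RNA genes had an SD 0.160 times that of Gm42418.

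Outlying libraries were sought in 344 groups of 4 day 14 values, for genes named in the text and for list means, by Dixon's test, and chance marks about 1 in 20 such groups. DMSO day 14 library 1 stood apart from its group with values of 11.48 for Mrc1, 9.36 for Vegfa, 9.47 for Pfkl, 6.41 for Rpl17-ps3 and 5.69 for Igkc, and with list means of 11.57 for MHC class II, 9.61 for dissociation and immediate-early genes and 5.42 for B and plasma cells. DMSO day 14 library 2 stood apart for mt-Co1 (11.37), Rnu3a (5.61) and Rps12-ps11 to Rps12-ps15 (5.88 each). DMSO day 14 library 3 stood apart for Dynlt1b (6.30) and Gys1 (9.10), and DMSO day 14 library 4 for Rpl18-ps2 (6.02). GSK day 14 library 1 stood apart for Rps12-ps11 to Rps12-ps15 (5.54 each) and for Rps12-ps17 and Rps12-ps18 (5.61 each), and GSK day 14 library 3 for Hsph1 (8.54). GSK day 14 library 4 stood apart for Ctss (15.08), AC061963.1 (4.75), Ifih1 (7.92), Itgb2 (10.15), Ccr2 (10.09) and the dissociation and immediate-early list mean (9.63).

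The pre-treatment difference itself differed between the days, by the interaction test, for Rps6-ps4 (5.09), for the 4T1 epithelium list (median -0.65) and for the mitochondrially encoded list (median 0.66). Both list calls ended with an estimated correlation (adjusted p = 0.767 each), did not pass in fry (adjusted p = 0.511 each) and had 0 members past the threshold over all genes in limma, with 2 each when adjusted over the list alone. Other splits of the libraries into groups of the same sizes called at most 4 genes against the real 1 for the interaction, in 5 of 100 splits at least as many, so chance cannot be excluded for that count.

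Chance is argued against for the day 14 count, where the real split called 1287 genes and the highest of the other splits called 1. The real split was the only 1 of 35 to call as many, the smallest share that 35 splits can give, so chance is not excluded. It is also argued against for the average over days (1724 against at most 1339, 1 of 100). The split that called 1339 left the day 14 groups whole and regrouped only day 8 libraries, so this says little about day 8. For time in GSK tumours the real split called 833 genes and the highest other 11 (1 of 35), which argues against chance with the same limit. These splits do not part pre-treatment or time from another feature that differs between the groups, such as the ribosomal RNA split. For time in DMSO tumours the real 98 genes stood against 94 in the split that parts libraries with AY036118 high from those with Gm42418 high; the real split was again 1 of 35, and with that feature as a term 115 genes passed, of which 94 were among the 98. On day 8 the 10 splits are too few for a share under 0.05, with 23 genes in the real split and at most 1 in the others. The correlation of day 8 and day 14 differences was 0.509 and the highest other absolute value was 0.551, with 5 of 100 splits at least as high, so chance cannot be excluded.

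Many genes differed on day 14, and a technical trend might produce that breadth. A GC trend as the whole cause is argued against by the correction, after which 85.1% of the called genes passed. Reads shared between near-identical genes are argued against as the main cause, since genes with under 1% of shared words were called 0.742 times as often on day 14 as genes with 10% or more, which does not hold for the 23 genes of day 8, where 13 were of the latter kind. The ribosomal RNA split as the whole cause is argued against by the 860 genes that passed among libraries with AY036118 high alone, though the split as a term left 362. The restriction to AY036118 high left 2 DMSO day 14 libraries, 1 and 3, and library 1 stood apart for several genes and list means. The ribosomal RNA share of the unlogged sum was still 3.61% and 6.49% in these and 2.62% to 4.62% in GSK day 14 libraries. The amount of that signal was thus not held equal and was not tested as a cause. The pre-treatment of the tumour cells and the make-up of the isolated fraction stay open, since with the 4T1 epithelium mean as a covariate 571 genes passed.

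Lrrc17 and Akap5 fell together after GSK pre-treatment on day 8, and across the 14 libraries their difference had an SD of 0.06 (Pearson 0.998). Lrrc17 shares 43 of its 31-base words with Akap5 and 37 with Gm26549, which changed by -1.39 (correlation with Lrrc17 over libraries 0.959), and 11 with Cnot3 (-0.96, correlation 0.915), so reads of a common sequence could account for these changes. The 7 genes other than Akap5 that share a word with Lrrc17, Gm26549 and Cnot3 included, had a median day 8 change of -0.38 (bootstrap SE over genes 0.255), with 6 of 7 lower, while on day 14, where Lrrc17 changed by -1.19, their median was 0.01 with 3 of 7 lower, 2 of them past the threshold (Gm26549 at -1.23 and Cnot3 at -1.11). The day 8 median lies below 0 by less than 2 SE, so the shared sequence and a change of either gene cannot be told apart, because too few genes share these words. A biological effect of pre-treatment on either gene was not tested apart from this.

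MHC class II genes were higher on day 14 than on day 8, and fewer cells of other types in the day 14 fractions could raise every macrophage gene. In DMSO tumours the median change of the class II list exceeded that of the pan-macrophage list by 0.461 (bootstrap SE over genes 0.221; permutation p = 0.00593 over 10 and 16 genes, which are not independent). Among these genes the excess was thus little more than 2 SE. Both measures are over genes and hold no spread between libraries, so they cannot decide the cause. DMSO day 14 library 1 stood apart for the class II list mean (11.57, against 11.14 to 11.19 in its group). The excess without that library was not computed, so fewer other cells as the whole cause are not excluded in DMSO tumours. In GSK tumours the same excess was 0.00822 (SE 0.214), so fewer other cells stay open there as well. Whether the excess differs between the pre-treatments was not tested. Time of tumour growth stays open as a biological explanation, as does a shift in which antigen-presenting cells the beads kept, neither of which was tested.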

How the results depend on the processing

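The GC correction, leaving out genes with shared sequence, the epithelium covariate, the ribosomal RNA term and restrictions, and leaving out the first library of both day 8 groups were chosen after the data were seen; the other settings were chosen before. Pseudocounts of 0.1 and 10, TMM rescaling, quantile normalisation and limma without the trend kept all 6 gene counts within 1.5 times. Counts are given in the order day 8, day 14, average, time in DMSO and time in GSK tumours where several stand together, and the cause was not tested unless said. Without the filter 0 (2907 at an unadjusted p under 0.05 in limma), 540, 951, 30 and 257 genes passed, with more genes tested; with a minimum of 50, 37 passed on day 8. Library quality weights gave 317, 2373, 2820, 19 and 3523. The replicate block gave 65 for time in DMSO and 301 for time in GSK tumours, and 4 for the interaction. Of 19 same-numbered pairs, 5 had a residual correlation over 0.1 (range -0.344 to 0.515). Of the 14 libraries, 5 correlated best with their own number. Pairs over 0.1 were not counted among differently numbered libraries, so the count of 5 cannot decide whether same-numbered libraries pair. A fit of only the groups compared gave 2 on day 8, 22 for time in DMSO and 1517 for time in GSK tumours. Removing the GC trend gave 58 on day 8, and leaving out genes with shared sequence gave 0 for the interaction in limma (738 at an unadjusted p under 0.05), since Rps6-ps4 was then not tested. The epithelium covariate gave 0 on day 8 (1809 at an unadjusted p under 0.05), 571 on day 14, 3 for time in DMSO and 1 for time in GSK tumours. Under it, of the genes and lists given here, time in GSK tumours reversed for Cavin1 (0.0596), Krt19 (0.19), Ccn1 (0.28), Plvap (0.63), Hba-a2 (0.29), Hba-a1 (0.47) and the endothelium list (0.28, adjusted p = 0.114), none past the threshold. In GSK libraries the covariate itself fell from 6.19 ± 0.62 (SD, n = 3) on day 8 to 4.83 ± 0.07 (SD, n = 4) on day 14. It thus takes up much of the difference between the days whatever the cause, and the loss of calls cannot tell causes apart. Krt19 is a member of the list and is adjusted partly by itself. The ribosomal RNA term gave 8, 362, 629 and, for time in GSK tumours, 471. With AY036118 high 76 passed on day 8, 26 for time in DMSO, 290 for time in GSK tumours and 12 for the interaction, with fewer libraries and only 1 in DMSO day 8; with Gm42418 high 3 passed on day 8, where 1 GSK library was left, and 1 for time in DMSO tumours, and no GSK day 14 library was left. Without the first library of both day 8 groups 45, 2089 and, for time in GSK tumours, 174 passed. Leaving out each library gave 0 to 208 on day 8, 221 to 1628 on day 14, 786 to 2299 for the average, 1 to 12 for the interaction, 24 to 305 for time in DMSO and 112 to 1218 for time in GSK tumours. The correlation of day 8 and day 14 differences ranged from 0.349 to 0.629 without single libraries; it was 0.612 with quality weights, 0.585 with the epithelium covariate, 0.405 with the ribosomal RNA term, 0.587 with AY036118 high and 0.659 without the first day 8 libraries. Every list call ended with an estimated correlation. DESeq2 was not run, since no counts were used here, and the unknown depth leaves open how much counting noise limits the low genes.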

Other observations

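No test in this part was chosen after the results were seen. Lists not described above are given here for GSK against DMSO tumours on day 14, as the mean log2-scale value ± SD (n = 4 each) in DMSO and then in GSK libraries. The T and NK cell list had a mean of 4.23 ± 0.11 and 4.22 ± 0.07, the dendritic cell list 5.97 ± 0.06 and 5.88 ± 0.04, the neutrophil list 7.87 ± 0.14 and 7.72 ± 0.18, and the erythroid list 5.00 ± 0.40 and 4.46 ± 0.20. In camera their adjusted p was 0.989, 0.660, 0.532 and 0.438. The list of eosinophils, basophils and mast cells had a mean of 5.29 ± 0.13 and 5.37 ± 0.11 (adjusted p = 0.760), and the fat pad list, which was not tested, 6.05 ± 0.19 and 5.68 ± 0.10. Nuclear genes of oxidative phosphorylation had a mean of 9.35 ± 0.10 and 9.55 ± 0.03, with 3 of 28 higher and 1 lower over all genes, 6 higher and 2 lower when adjusted over the list alone (adjusted p = 0.431). The matrix and angiogenic list had 2 of 23 higher and 1 lower, 5 higher and 1 lower when adjusted over the list alone (adjusted p = 0.451), and the interferon list 2 of 32 higher and 1 lower by both adjustments (adjusted p = 0.268). The unfolded protein response list had 1 of 18 higher and 1 lower, 1 higher and 2 lower when adjusted over the list alone (adjusted p = 0.760). The adjusted p was 0.431 for MHC class I, 0.784 for monocyte genes, 0.908 for CC chemokines and 0.775 for cell cycle genes.

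By fry, which tests a list against no change and not against other genes, 0 lists passed on day 8, on day 14 and for the interaction (lowest adjusted p = 0.0597, 0.0939 and 0.511), so no camera call of these 3 comparisons passed in fry. For the average over days 4 lists passed, for time in DMSO tumours 1 and for time in GSK tumours 7. For time in GSK tumours the pan-macrophage and endothelium calls of camera did not pass (fry adjusted p = 0.0514 and 0.0688), and the 7 include dendritic cell markers (median -0.22, fry adjusted p = 0.0253) and erythroid genes (median -1.44, fry adjusted p = 0.0345), neither of which passed in camera (adjusted p = 0.0836 each). The summed signal of the ribosomal RNA genes AY036118 and Gm42418 was 2.62% to 13.6% of the unlogged sum of a library. It was 2.62% to 6.57% in the 9 libraries with AY036118 high and 7.57% to 13.6% in the 5 with Gm42418 high. The split thus goes with the amount of this signal as well as with the gene that holds it. On day 14 this share was 2.62% to 4.62% in GSK and 3.61% to 12.8% in DMSO libraries.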
